A study of Homo sapiens with 6 samples.

How the data were processed

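RNA was sequenced from MDA-MB-453, an established human breast cancer cell line, in 6 libraries: 3 from cells that received a control vector and 3 from cells that received a construct for overexpression of ZNF207. The design text describes the 3 libraries of each group as separate biological replicates. Replicate numbers come from the sample titles. The columns of the deposited table do not carry these titles: columns named NC were taken as the control vector and columns named 207 as the ZNF207 construct, with the final digit of each name as the replicate number. This match rests on the names alone, and every value of a single library or without one depends on it.

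The deposited table holds FPKM values, fragment numbers scaled by transcript length and by the mapped fragments of the library, with 1 column per library and no pooling of replicates. Per the submitters' processing notes, Bowtie2, RSEM 1.3.1 and DESeq2 1.4.5 were used on genome build hg38. The role of each tool, the annotation release, the library kit's strand and any filter are not given in the sources used here. The table has 60658 rows for 60569 gene names. Where a name had several rows, the row with the highest mean was kept. The table lists a locus per row, and 37863 rows share theirs with another row, so a listed locus can span several overlapping genes. Gene coordinates were therefore taken from GENCODE v29 on GRCh38 where the named gene lay in the listed locus, and are otherwise left out.

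FPKM values are not counts, so no count test was used. Read depth is unknown: low values were searched for the steps that whole reads would leave, and at most 0.765% of 1438 low genes shared a ratio between a pair of libraries. Intervals and detection limits that need read numbers are not given. No 2 libraries of a group had more than 8 tested genes with identical values, so each library was counted as its own replicate.

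Values were analysed as log2(FPKM + 1) for the 13185 genes with an FPKM of 1 or more in at least 3 libraries. A log2 change on this scale understates the change of low genes. The groups were compared with limma 3.58.1 in R 4.3.3 (linear model, moderated with a mean-variance trend, two-sided), with Benjamini-Hochberg adjustment over all tested genes and a threshold of 0.05. All adjusted p-values of genes are from this test. An exact two-sided permutation test of 3 against 3 libraries cannot give a p below 0.1, and is given for ZNF207 and GH1. On simulated data with the means and spreads of these libraries (12982 genes tested), the same procedure recovered 70% of 50 genes changed by 0.5 on the log2 scale, 92% of 50 changed by 1 and 100% of those changed by 2 or 3. It made 13 false calls beside these, and 0 calls in a simulation without effects. The changed genes were drawn only from genes above a minimum level, and more were changed than were called here, which eases the adjustment. Noise was independent between genes. The shares recovered may therefore be too high for the real libraries, and the false calls do not cover correlated genes.

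There were 37 gene lists, written from general knowledge of the line, of mitosis, of stress responses and of cell types that could be mixed in. The 34 lists with at least 5 tested members were tested with camera in limma, with a preset correlation of 0.01 between genes and Benjamini-Hochberg adjustment over lists. Camera with a correlation estimated from the data, and fry, which asks whether the genes of a list move on balance one way, were run beside it. Counts of members "adjusted over the list alone" use the same gene p-values with the adjustment made within the list.

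The genes named in the text were chosen by a rule: ZNF207, then a few genes including BUB3, ERBB2, ESR1 and MKI67 whatever their change, then the 8 largest rises and the 8 largest falls among called genes with a mean FPKM of 2 or more in a group and no overlap between groups, then up to 3 called members of each list, or the 2 members with the smallest p for a called list without any. Some genes that this rule takes, and 1 gene list, are not reported here. Genes named outside this rule are marked as chosen after their values were seen. The comparison, lists, naming rule and alternatives were fixed before the data were examined. The alternatives were another pseudocount, filter, scaling, variance model or library weighting, the replicate number as a block, and each library left out in turn.

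Transcripts of genes with a close copy were compared with BLAST 2.17.0. Values of genes with paralogs or processed pseudogenes, of overlapping genes and of antisense genes are uncertain, since the assignment of shared reads is not described in the sources used here. This covers the histone genes, AKR1C2, the ribosomal protein genes, GAPDH, and PSMB9 and TAP1, which share a listed locus.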

Results

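The transcriptome of MDA-MB-453 breast cancer cells was measured by RNA sequencing after transfection with a control vector (3 libraries) or a ZNF207 construct (3 libraries). ZNF207, also called BuGZ, is a zinc finger protein that binds microtubules and carries the checkpoint protein BUB3 to kinetochores. The libraries held 13061 to 13231 genes at an FPKM of 1 or more, and FPKM summed to between 589360 and 612711 per library. Pearson correlations of log2 values between libraries, taken across genes, ranged from 0.9845 to 0.9912. The first principal component held 31.4% of the variance and parted the groups, with control libraries between -16.3 and -3.52 and overexpression libraries between 5.06 and 18.5.

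The comparison asked which transcripts differed when ZNF207 was overexpressed. ZNF207 itself (chromosome 17, 32350117 to 32381886, plus strand, GRCh38) stood at 66.6 ± 2.78 FPKM in controls and 807 ± 69.9 FPKM in overexpression libraries (SD, n = 3 each), a 12.1-fold higher mean. The controls were at 69.2, 67.0 and 63.7 FPKM and the overexpression libraries at 885, 786 and 750 FPKM. Its log2 change was 3.58 (SE 0.07, limma adjusted p = 4.03e-09), and the exact permutation p was 0.1, the smallest that 3 against 3 libraries allow. BUB3, its partner at kinetochores, had a log2 change of 0.01 (adjusted p = 0.951). The oestrogen receptor gene ESR1 stood at 18.5 ± 1.59 and 25.9 ± 6.21 FPKM in controls and overexpression libraries (log2 change 0.44, SE 0.15, adjusted p = 0.269), and its log2 change was 0.27 without overexpression replicate 3 (adjusted p = 0.541). ERBB2, a receptor tyrosine kinase, had 0.06 (adjusted p = 0.76) and the proliferation marker MKI67 had -0.03 (adjusted p = 0.917). Over 17 alternatives the log2 change ran from -0.01 to 0.05 for BUB3, 0.27 to 0.61 for ESR1, 0.00 to 0.09 for ERBB2 and -0.08 to 0.02 for MKI67, none of them past the threshold.

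Beyond ZNF207, members of the hypoxia and glycolysis gene list made up 11 of the 21 genes that fell, and 6 other genes rose. In all, 28 of 13185 genes changed (limma, adjusted p under 0.05), 7 up and 21 down, and 6 of them changed at least 2-fold on the log2(FPKM + 1) scale, 4 up and 2 down. These 6 were ZNF207, GH1, AC005899.5, AC099336.2 and 2 rows described under other observations. What the last 4 measure is uncertain, for reasons given where each is described. At an unadjusted p under 0.05 there were 670 higher and 927 lower genes. The number of changed genes moved when 1 library was left out, which also leaves fewer samples. It was 36, 9 and 14 without control replicates 1, 2 and 3. Without overexpression replicates 1, 2 and 3 it was 9, 15 and 4. With quantile scaling 8 genes rose and 12 fell, and with median-of-ratios scaling 6 rose and 11 fell.

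The largest fall was that of GH1, the pituitary growth hormone gene (chromosome 17, 63917200 to 63918838, minus strand). It stood at 115, 93.8 and 93.8 FPKM in the controls, and in the overexpression libraries it was listed at 0, 0.275 and 0 FPKM. Its log2 change was -6.55 (SE 0.13, adjusted p = 4.03e-09, exact permutation p = 0.1). Its near-identical paralogs GH2, CSH2 and CSHL1 were listed at 0 in all 6 libraries, and CSH1 reached 0.139 FPKM in 1 control.

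Enzymes of glycolysis fell with ENO2, a neuronal enolase isoform, from 46.8 ± 5.58 to 25.7 ± 1.44 FPKM (log2 change -0.84, SE 0.09, adjusted p = 0.00644) and ALDOC, an aldolase isoform, from 127 ± 12.4 to 73.2 ± 2.63 FPKM (-0.79, SE 0.07, adjusted p = 0.00383). NDRG1, a gene induced by hypoxia, fell from 173 ± 23.1 to 102 ± 14.6 FPKM (-0.75, SE 0.12, adjusted p = 0.047). PDK1, a kinase that inhibits pyruvate dehydrogenase, fell from 31.1 ± 1.74 to 19.9 ± 1.48 FPKM (-0.62, SE 0.08, adjusted p = 0.018). LOX, which crosslinks collagen and elastin, fell from 11.2 ± 0.773 to 5.29 ± 0.307 FPKM (-0.95, SE 0.09, adjusted p = 0.00414), and its relative LOXL2 from 29.5 ± 2.91 to 18.5 ± 1.64 FPKM (-0.65, SE 0.09, adjusted p = 0.0331). DPYSL4, a member of the dihydropyrimidinase-like family, fell from 13.2 ± 1.13 to 7.84 ± 0.565 FPKM (-0.68, SE 0.09, adjusted p = 0.0288). NDRG1 and LOXL2 lost their calls with TPM, median-of-ratios and quantile scaling (adjusted p 0.0547 to 0.0763). Without a variance trend all these genes but LOX lost theirs (0.0749 to 0.172), and without a filter all of them did, LOX included (0.0657 to 0.308). Several calls were also lost when 1 library was left out, which leaves fewer samples. That of ENO2 was lost without overexpression replicate 3 (adjusted p = 0.0585). PDK1 lost its call without control replicate 2, overexpression replicate 1 or overexpression replicate 3 (adjusted p 0.0589 to 0.0915), NDRG1 without these or control replicate 1 (0.0743 to 0.157), DPYSL4 without any library but control replicate 1 (0.0529 to 0.134) and LOXL2 without any of the 6 (0.0518 to 0.134).

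**Figure D1:**
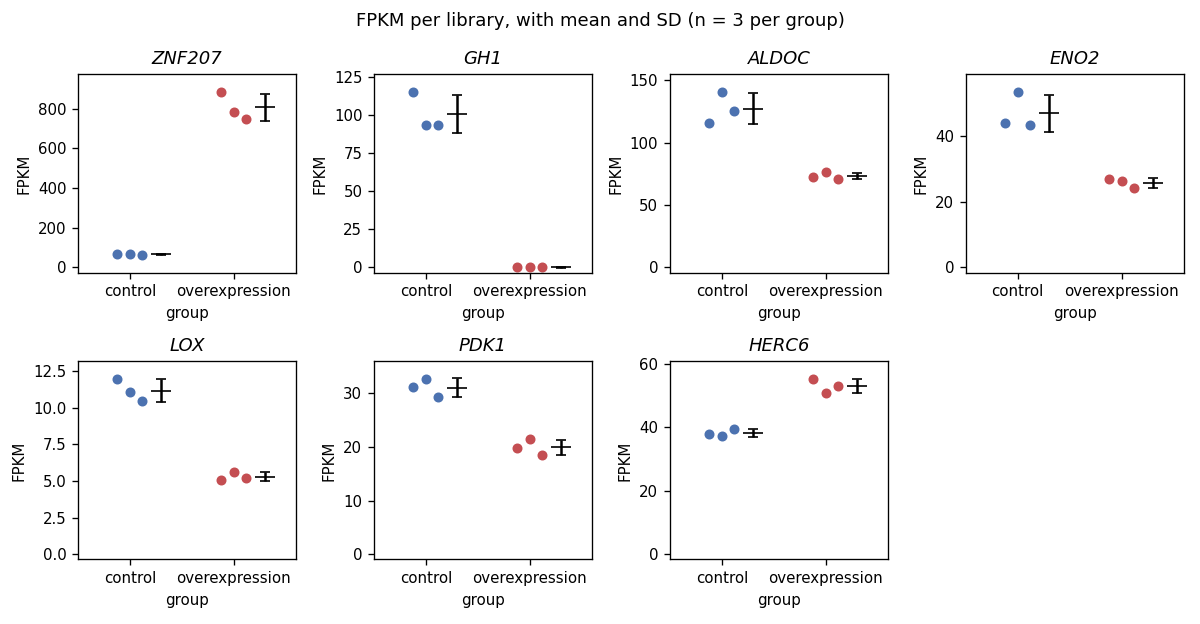
FPKM of 7 genes in each library, for control (blue) and overexpression (red) libraries. Points are libraries, and the bar beside them is the mean with the SD (n = 3). ZNF207 rises from 66.6 to 807 FPKM on average, and LOX falls from 11.2 to 5.29 FPKM.

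Few genes rose. HERC6, an interferon-induced member of the HERC family, rose from 38.2 ± 1.26 to 53.1 ± 2.22 FPKM (log2 change 0.46, SE 0.06, adjusted p = 0.0196). AC093001.1, annotated as antisense on chromosome 3 (149284782 to 149333653), rose from 15.7 ± 0.546 to 22.4 ± 1.65 FPKM (0.49, SE 0.08, adjusted p = 0.047). AC005899.5, whose listed locus is that of ZNF207, was listed at 0 in the 3 controls and at 33.0, 9.19 and 43.1 FPKM in the overexpression libraries (adjusted p = 0.00384). AC099336.2, a processed pseudogene on chromosome 1 (202471864 to 202472117), was listed at 0 in the 3 controls and at 2.64, 3.72 and 3.17 FPKM in the overexpression libraries (adjusted p = 0.00137). Its sequence is 99.2% identical to RPS27 over 254 bases, so its value is uncertain. HERC6 lost its call without control replicate 2, overexpression replicate 1 or overexpression replicate 3 (adjusted p 0.0863 to 0.112), and AC093001.1 without any of the 6 libraries (0.0708 to 0.153). AC093001.1 also lost its call with TPM, median-of-ratios and quantile scaling (0.0597 to 0.0639). Without a variance trend HERC6 (0.14), AC093001.1 (0.144) and AC005899.5 (0.0749) were not called. AC005899.5 also lost its call with a robust variance model (0.0695). The calls of HERC6 (0.0926), AC093001.1 (0.178) and AC005899.5 (0.139) were lost without a filter.

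The list of hypoxia and glycolysis genes had 29 tested members, of which 0 rose, 11 fell and 18 did not pass the test. Adjusted over the list alone, 28 fell. All 29 estimates were below 0, and the median log2 change was -0.47. Camera with the preset correlation gave an adjusted p of 9.82e-39, and the adjusted p was 0.341 with an estimated correlation. The mean log2 level of the list lay between 7.27 and 7.48 in the controls and between 6.71 and 6.93 in the overexpression libraries.

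**Figure D2:**
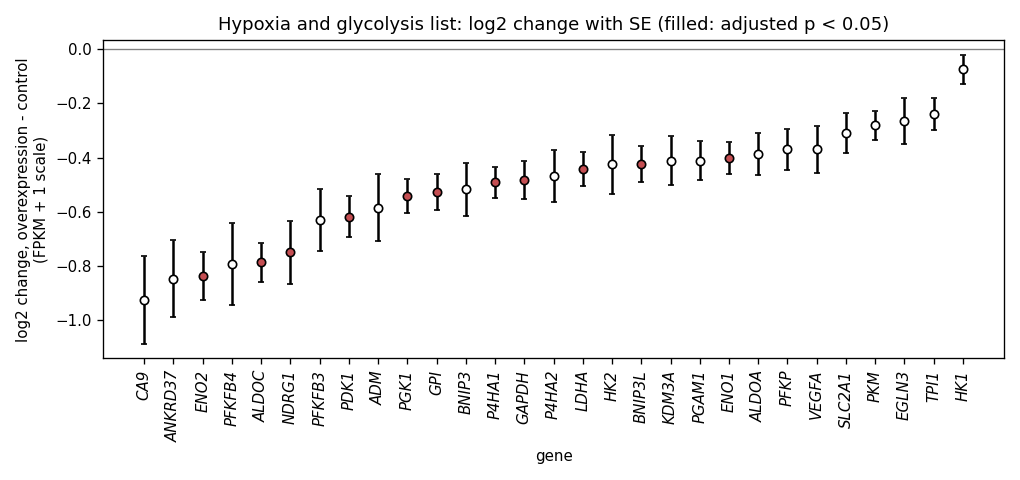
Log2 change (overexpression minus control, FPKM + 1 scale) of the 29 tested hypoxia and glycolysis genes, with the SE from limma. Filled points are the 11 genes that passed the threshold over all genes, and all 29 points lie below 0.

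The interferon response list had 35 tested members, of which 1 rose, HERC6, and 0 fell. Adjusted over the list alone, 25 rose. Its median log2 change was 0.23, with an adjusted p of 6.59e-21 from camera and an adjusted p of 0.138 with an estimated correlation. In the antigen presentation list 0 of 16 members passed the test, 7 rose when adjusted over the list alone, and the median was 0.20 (camera adjusted p = 6.87e-06, and adjusted p = 0.318 with an estimated correlation). PSMB9, an immunoproteasome subunit, stood at 14.3 ± 0.878 and 19.8 ± 1.47 FPKM in controls and overexpression libraries (adjusted p = 0.0714), and TAP1, a peptide transporter, at 80.1 ± 3.77 and 98.0 ± 2.11 FPKM (adjusted p = 0.0786). None of 19 NF-kB and inflammatory genes passed the test, and 6 rose when adjusted over the list alone (median 0.14, camera adjusted p = 9.8e-06, and adjusted p = 0.404 with an estimated correlation). The chemokine CXCL8 stood at 4.03 ± 0.366 and 7.42 ± 1.12 FPKM (adjusted p = 0.0541) and the NF-kB inhibitor NFKBIA at 111 ± 5.11 and 135 ± 4.69 FPKM (adjusted p = 0.0848). The NF-kB median was 0.28 without control replicate 1, 0.21 without overexpression replicate 3 and 0.22 with the filter at an FPKM of 5.

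Of 26 DNA replication and G1/S genes, 1 fell and 8 fell when adjusted over the list alone. All 26 estimates were below 0 (median -0.15, camera adjusted p = 4.37e-11, and adjusted p = 0.341 with an estimated correlation). The 27 spindle checkpoint and kinetochore genes included 0 that passed the test by limma or when adjusted over the list alone (1 higher and 2 lower at an unadjusted p under 0.05), with a median of 0.02, a mean of -0.01 and a camera adjusted p of 0.816. The 20 G2/M genes had 0 that passed when adjusted over the list alone (1 higher and 1 lower at an unadjusted p under 0.05 by limma) and a median of 0.00 (adjusted p = 0.68). Of 15 histone genes none passed the test, and 2 rose when adjusted over the list alone (median 0.05, camera adjusted p = 0.0339, and adjusted p = 0.341 with an estimated correlation). H2BC12 stood at 208 ± 1.92 and 250 ± 10.9 FPKM (adjusted p = 0.0819) and H2BC4 at 25.3 ± 3.39 and 33.8 ± 4.58 FPKM (adjusted p = 0.204). The histone call was lost without a filter (adjusted p = 0.0525) and without control replicate 1, control replicate 3, overexpression replicate 1 or overexpression replicate 2 (0.0558 to 0.204). Its median was 0.03 without control replicate 1 or overexpression replicate 2, 0.08 without control replicate 2 and 0.13 without overexpression replicate 3.

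The 13 mitochondrially encoded genes all had estimates above 0, with 0 past the threshold and 8 that rose when adjusted over the list alone (median 0.27, camera adjusted p = 1.64e-08, and adjusted p = 0.364 with an estimated correlation). MT-ATP8, an ATP synthase subunit, stood at 3428 ± 696 and 5256 ± 823 FPKM (adjusted p = 0.137) and MT-CO3, a cytochrome c oxidase subunit, at 1097 ± 174 and 1477 ± 157 FPKM (adjusted p = 0.169), and both share a listed locus. Their list took 4.36% to 5.42% of FPKM in controls and 5.71% to 6.64% in overexpression libraries. The 39 nuclear oxidative phosphorylation genes had 0 that passed when adjusted over the list alone (3 lower at an unadjusted p under 0.05 by limma) and a median of -0.04 (adjusted p = 0.357). All 42 cytosolic ribosomal protein genes had estimates below 0, with 0 past the threshold over all genes or over the list alone and 12 lower at an unadjusted p under 0.05 (median -0.12, camera adjusted p = 5.23e-10, and adjusted p = 0.448 with an estimated correlation). RPS14 stood at 898 ± 29.9 and 803 ± 27.9 FPKM (adjusted p = 0.268) and RPS29 at 1367 ± 85.6 and 1184 ± 78.9 FPKM (adjusted p = 0.269). The ribosomal median was -0.04 with quantile scaling (camera adjusted p = 0.00318), -0.08 without control replicate 2, and -0.04 once a trend with expression level, transcript length and GC content was removed. Ribosomal protein genes took 7.79% to 8.65% of FPKM in controls and 7.43% to 7.90% in overexpression libraries.

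Camera also called stress and metabolic lists with small medians. Cholesterol synthesis genes (22 tested, 1 rose when adjusted over the list alone) had a median of 0.11 (camera adjusted p = 1.95e-05, and adjusted p = 0.341 with an estimated correlation). SQLE, squalene epoxidase, stood at 122 ± 2.33 and 151 ± 5.21 FPKM (adjusted p = 0.0527). NRF2 targets (23 tested, 6 higher at an unadjusted p under 0.05) had a median of 0.14 (adjusted p = 3.99e-05, and adjusted p = 0.448 with an estimated correlation), with AKR1C2 at 12.9 ± 0.707 and 18.0 ± 3.06 FPKM (adjusted p = 0.153). The unfolded protein response list (19 tested, 4 up and 1 down when adjusted over the list alone) had a median of 0.08 (adjusted p = 0.00029, and adjusted p = 0.404 with an estimated correlation). In it the chaperone gene DNAJB9 stood at 70.5 ± 4.62 and 92.3 ± 9.31 FPKM (adjusted p = 0.0958) and PDIA3 at 195 ± 10.7 and 160 ± 9.01 FPKM (adjusted p = 0.108). Heat shock genes (15 tested, 3 higher at an unadjusted p under 0.05) had a median of 0.07 (adjusted p = 0.00619, and adjusted p = 0.448 with an estimated correlation), with HSPH1 at 69.0 ± 7.81 and 85.9 ± 7.47 FPKM (adjusted p = 0.206) and DNAJA1 at 127 ± 5.55 and 145 ± 5.63 FPKM (adjusted p = 0.23). Apoptosis regulators (25 tested, 1 down when adjusted over the list alone) had a median of 0.09 (adjusted p = 0.0389, and adjusted p = 0.404 with an estimated correlation), with APAF1 at 10.7 ± 1.18 and 7.30 ± 0.288 FPKM (adjusted p = 0.0848) and CASP9 at 2.27 ± 0.284 and 3.18 ± 0.263 FPKM (adjusted p = 0.306). The apoptosis call was lost with the filter at an FPKM of 5 (median 0.05, adjusted p = 0.216) and without any library but control replicate 3 (0.0816 to 0.128). Its median was 0.05 without control replicate 1, 0.06 without control replicate 2 and 0.05 without overexpression replicate 3. Without control replicate 1 and without overexpression replicate 3 the NRF2 median was 0.09 and 0.08. Without control replicate 2 and without overexpression replicate 3 the heat shock median was 0.03 and 0.04, and it was 0.04 without a filter. The median of the unfolded protein response list was 0.13 without control replicate 3 and 0.13 with quantile scaling.

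Lists that camera called lower included mesenchymal and EMT genes (10 tested), in which 1 fell, LOX, and 2 fell when adjusted over the list alone (median -0.19, adjusted p = 0.00619, and adjusted p = 0.341 with an estimated correlation). That call was lost without a filter (median -0.05, adjusted p = 0.285), and the median was -0.31 with a pseudocount of 0.1 and -0.08 without overexpression replicate 2. ATF4 stress response genes (25 tested, 1 up and 6 down when adjusted over the list alone) had a median of -0.06 (adjusted p = 0.0125, and adjusted p = 0.647 with an estimated correlation), with WARS1 at 130 ± 1.49 and 155 ± 1.97 FPKM (adjusted p = 0.0672) and DDIT4 at 617 ± 79.7 and 449 ± 47.1 FPKM (adjusted p = 0.108). The ATF4 list shares a lower member with the hypoxia and glycolysis list, so these lists are not fully independent. The ATF4 call was lost without control replicate 2, control replicate 3 or overexpression replicate 1 (adjusted p 0.0643 to 0.193). Its median was -0.15 without control replicate 1, and -0.02, -0.10 and -0.13 without overexpression replicates 1, 2 and 3. ERK pathway output genes (13 tested, 1 up and 4 down when adjusted over the list alone) had a median of -0.14 (adjusted p = 0.0334, and adjusted p = 0.404 with an estimated correlation), with DUSP5 at 11.2 ± 0.878 and 14.9 ± 0.866 FPKM (adjusted p = 0.111) and IER3 at 79.4 ± 5.98 and 64.7 ± 3.62 FPKM (adjusted p = 0.13). The ERK call was lost without a filter (adjusted p = 0.108), with the filter at an FPKM of 5 (0.125), after rescaling to TPM (median -0.07, 0.0967) and without control replicate 1, control replicate 2 or overexpression replicate 3 (0.0558 to 0.172). Its median was -0.07 without control replicate 2 and -0.08 without overexpression replicate 3. FOXO and PI3K feedback genes (20 tested, 4 down when adjusted over the list alone) had a median of -0.09 (adjusted p = 0.0431, and adjusted p = 0.564 with an estimated correlation), with TXNIP at 722 ± 4.78 and 610 ± 17.3 FPKM (adjusted p = 0.0881) and PIK3IP1 at 10.4 ± 0.636 and 7.84 ± 0.498 FPKM (adjusted p = 0.131). The FOXO and PI3K call was lost with the filter at an FPKM of 5 (adjusted p = 0.125), with quantile scaling (0.0528) and without any control library or overexpression replicate 1 (0.0547 to 0.321).

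In all, camera with the preset correlation called 17 of 34 lists, 10 up and 7 down. With an estimated correlation it called 0 (smallest adjusted p = 0.138), and fry called 1, the interferon response list (adjusted p = 0.021). At an unadjusted p under 0.05 the preset test passed 19 lists, the one with an estimated correlation 3 and fry 9. Estimated correlations among the called lists ran from -0.0055 for histone genes to 0.7301 for hypoxia and glycolysis genes. The preset value was 0.01. Mean log2 levels per library overlapped between groups for the histone, NF-kB, apoptosis, NRF2, ATF4 and ribosomal lists. For the other called lists they did not overlap.

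**Figure D3:**
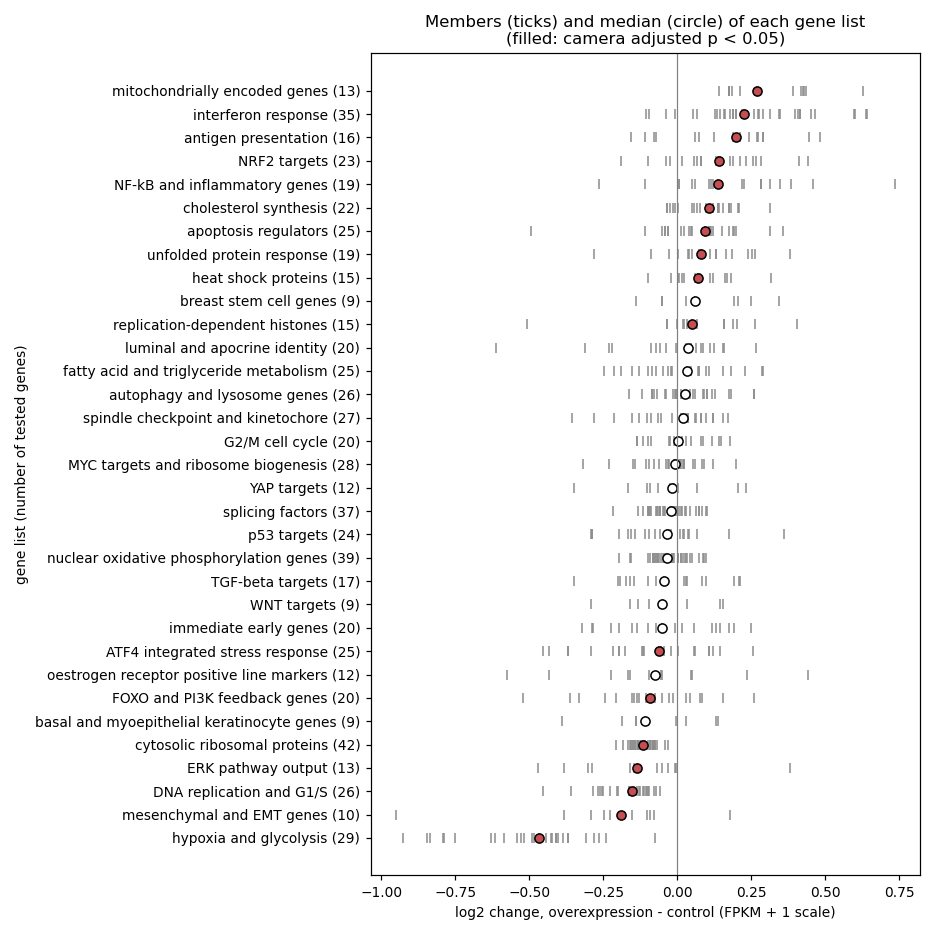
Log2 change (overexpression minus control, FPKM + 1 scale) of the tested members of the gene lists (ticks) and the median of each list (circle). Filled circles are the 17 lists called by camera with the preset correlation, and the hypoxia and glycolysis list has the lowest median, -0.47.

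The other lists reported here did not pass camera's threshold. Luminal and apocrine identity genes (20 tested, 3 down when adjusted over the list alone) had a median of 0.04 and a mean of -0.02 (adjusted p = 0.99). Oestrogen receptor positive line markers (12 tested, 1 up and 5 down when adjusted over the list alone) reached 1198 FPKM and had a median of -0.08 (adjusted p = 0.0563), and the list was called without control replicate 2 (median -0.12, adjusted p = 0.00738). Their levels were not compared with those known for the line, so the identity of the cells rests on the labels. Medians were -0.11 for basal and myoepithelial genes (adjusted p = 0.411), 0.06 for breast stem cell genes (adjusted p = 0.0892), -0.05 for immediate early genes (adjusted p = 0.597) and -0.03 for p53 targets (adjusted p = 0.242). Adjusted over the list alone, 1 immediate early gene and 1 fatty acid and triglyceride gene fell and 1 p53 target rose, while the basal, stem cell, autophagy, MYC, splicing, TGF-beta, WNT and YAP lists had 0 either way. At an unadjusted p under 0.05 by limma, these 8 lists had 0, 3, 1, 0, 0, 1, 0 and 0 higher and 1, 0, 1, 2, 1, 3, 1 and 1 lower genes. The stem cell list was called without overexpression replicate 3 (median 0.09, adjusted p = 0.0305), and autophagy and lysosome genes without control replicate 3 (0.07, adjusted p = 0.037) or overexpression replicate 1 (0.07, adjusted p = 0.0317). Fatty acid and triglyceride genes had 0.03 (adjusted p = 0.518), autophagy and lysosome genes 0.03 (adjusted p = 0.192), MYC and ribosome biogenesis genes -0.01 (adjusted p = 0.695) and splicing factors -0.02 (adjusted p = 0.518). For TGF-beta, WNT and YAP targets the medians were -0.04 (adjusted p = 0.754), -0.05 (adjusted p = 0.518) and -0.02 (adjusted p = 0.809). Markers of other cell types were too low to test as lists. Of 12 fibroblast markers 2 were tested, and none exceeded 11.3 FPKM in any library. No leukocyte marker of 14 exceeded 1.395 FPKM, and no endothelial marker of 10 exceeded 1.76 FPKM.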

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

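The alternatives were fixed before the data were examined, except the order of libraries in fry, added after seeing the data. ZNF207 was higher and past the threshold in each of 17 alternatives (log2 change 3.51 to 3.63), and none of the 28 changed genes changed sign in the 12 that can move a gene's estimate, nor any median of the 17 called lists in the 14 that can move one, wherever they were tested. The others alter only the test or the genes tested. The groups did not overlap in any of the 28 genes, so a left-out library, another pseudocount or weights could not turn a sign. For these genes only the 3 other scalings could have done so. Uncalled values near 0 did change sign. Of the 28 changed genes, 3 stayed past the threshold in every alternative that tested them: ZNF207 (17 alternatives), GH1 (14) and AC099336.2 (13). GH1 was below the filter, and so untested, whenever a control was left out. AC099336.2 was untested whenever an overexpression library was left out and with the filter at an FPKM of 5. The number of changed genes was 4 without a filter on low values, 64 with an FPKM of 5 or more in 3 libraries, 18 after rescaling to TPM, 17 with median-of-ratios size factors and 5 without a variance trend. Leaving out 1 library gave 4 to 36 genes, 19 of the 36 shared with the 28. The number changed at least 2-fold was 3 without a filter and 3 with the stricter one, and 2 to 6 without 1 library (3 without control replicate 3, 2 without overexpression replicate 2 and 2 without overexpression replicate 3). The cause was not tested, except that filters change how many genes are tested and a left-out library leaves fewer samples.

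Camera with an estimated correlation called 0 lists and fry called 1, and for the hypoxia and glycolysis list, with its median of -0.47, their adjusted p was 0.341 and 0.0672. Over 19 alternatives that median ran from -0.50 to -0.42, with adjusted p from 1.96e-39 to 0.341. Fry also called 1 list with the library order reversed and 1 with overexpression libraries entered first, and its adjusted p for the interferon list moved with that order, from 0.021 to 0.0283. Leaving out 1 library gave 13 to 16 called lists.

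With the replicate number as a block 145 genes changed (56 up, 89 down), all 28 among them, and 17 lists were called, 16 of them shared: FOXO and PI3K feedback genes were not among them (adjusted p = 0.107) and oestrogen receptor positive line markers were (0.0363). Same-numbered libraries deviated together with correlations of 0.136, 0.009 and 0.175, and other pairs with -0.209 to 0.071. Controls 1 and 3 correlated best with the overexpression library of their number, but control 2 with overexpression 1 (0.071). Whether the numbers pair the libraries stays open, and the fit without a block was kept. Depth is unknown, so how it limits low genes cannot be given.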

Other observations

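The limma comparison and the 3 other scalings were fixed before the data were examined. The use of these scalings to test an explanation, the tests on paralogs, flanking genes, genes within 1 Mb, the trend, parts of the hypoxia list, ratios to ZNF207 and shared sequence, and the comparison with other splits were chosen after the results were seen. So were the genes named here that the report does not name, which are given singly. P4HA1, a subunit of collagen prolyl hydroxylase and a member of the hypoxia list, fell from 167 ± 4.79 to 118 ± 6.37 FPKM (SD, n = 3 each; limma adjusted p = 0.012), and PLOD1, a lysyl hydroxylase, from 56.6 ± 3.54 to 42.4 ± 1.25 FPKM (adjusted p = 0.0469). QSOX1, a secreted enzyme that forms disulfide bonds, fell from 111 ± 10.2 to 74.6 ± 3.80 FPKM (adjusted p = 0.02). MAPT, which encodes tau, fell by 0.52 and TUBA1A, an alpha tubulin, by 0.40 on the log2 scale (adjusted p = 0.0469 and 0.049). BNIP3L, a mitophagy receptor also in the hypoxia list, fell by 0.42 (adjusted p = 0.047).

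Of 8 genes often used to normalise quantitative PCR, 1 changed, and differences between the 8 were not tested. GAPDH fell from 3844 ± 239 to 2750 ± 149 FPKM (log2 change -0.48, adjusted p = 0.0379), and so did the glycolytic genes PGK1 (-0.54, adjusted p = 0.0145) and LDHA (-0.44, adjusted p = 0.0331). ACTB had -0.03 (adjusted p = 0.882), PPIA 0.00 (adjusted p = 0.984), TBP -0.01 (adjusted p = 0.983) and YWHAZ 0.04 (adjusted p = 0.839). HPRT1 had -0.23 (adjusted p = 0.114), GUSB -0.18 (adjusted p = 0.303) and RPLP0 -0.13 (adjusted p = 0.387), each with an unadjusted p under 0.05. SNHG25, a small nucleolar RNA host gene within 1 Mb of GH1, was listed at 493 FPKM in overexpression replicate 1 and at no more than 4.42 FPKM in the other 5 libraries. AL133461.1, listed at 1.93, 1.44 and 1.37 FPKM in controls and at 0 in all overexpression libraries, is 100% identical to INPP5F over 268 bases, and AP003392.5 was the other gene changed at least 2-fold that the report does not name (log2 change 1.30, adjusted p = 0.043), though its listed locus is not that of the GENCODE v29 gene of this name, so what it measures is uncertain.

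GH1 was near 100 FPKM in each control and near 0 after overexpression, which no other gene of the table matched in size of fall. Reads shifted to its paralogs are argued against, since GH2, CSH1, CSH2 and CSHL1 summed to 0 FPKM in each overexpression library. Loss or silencing of the whole region is argued against by the 22 tested genes within 1 Mb, whose median log2 change was 0.0164 with 0 called. A loss or silencing confined to GH1 and its nearest genes was not tested, since those genes were near 0 in the controls too. A growth hormone sequence carried by the control vector, such as the polyadenylation signal of some expression plasmids, may be a source. The ZNF207 construct would have to lack it, since GH1 was listed at 0, 0.275 and 0 FPKM in the overexpression libraries. The flanking genes CD79B and SCN4A and the paralogs stayed at or below 0.388 FPKM in the controls, but endogenous GH1 alone could give that too. The sequences of the vector and the construct and the reads were not analysed here. An effect of ZNF207 on GH1 stays open and untested.

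The lower hypoxia and glycolysis genes are a second pattern. Scaling as the whole cause is argued against, since the list median was -0.42 at its closest to 0 under TPM, median-of-ratios and quantile scaling. A trend with expression level, transcript length and GC content is argued against in the same way: with it removed the list median was -0.43, while that of ribosomal protein genes moved from -0.12 to -0.04. The 12 members that are not glycolytic enzymes or transporters had a median of -0.50 and the 17 others -0.43, which decides nothing, since all 29 members had been seen to lie below 0. Whether the lower values come from ZNF207 or from oxygen, cell density or medium that may have differed between cultures cannot be told apart, because each group is its own set of cultures.

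AC005899.5 was listed at 0 in the controls and at 9.19 to 43.1 FPKM in overexpression libraries, in the listed locus of ZNF207. Raised transcription of the whole region is argued against by the 13 other tested genes within 1 Mb, with a median log2 change of -0.024 and 0 called. A fixed share of ZNF207 reads is argued against too: the ratio in the overexpression libraries, 1.17% to 5.75%, predicts 2.36 FPKM on average in the controls and at least 0.745 FPKM in each. Reads from the construct itself may have been assigned to an overlapping gene: AC005899.4, which GENCODE v29 places over ZNF207, shares 77.7% of its 31-base words with ZNF207 transcripts, but the annotation behind the deposited name is not given in the sources used here, so this stays open.

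The 6 libraries can be split 3 against 3 in 10 ways, too few for a share under 0.05. The number of changed genes was 28 in the real split and at most 4 in the others, and the number changed at least 2-fold was 6 and at most 4. Camera with the preset correlation called 17 lists in the real split and up to 13 in the others, and the size of the hypoxia and glycolysis median was 0.47 and at most 0.23. In each of these 4 results, 1 of the 10 splits, the real one, gave a value as large.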
